A study of Mus musculus with 36 samples.

How the data were processed

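Liver RNA of Swiss Webster mice had been made into TruSeq RNA v2 libraries, 1 per sample, and sequenced on an Illumina HiSeq. Per the labels, reads were processed with CASAVA 1.8.2 and aligned with TopHat2 2.0.12 to the mouse genome build GRCm38. The deposited counts are whole read counts for 27505 Ensembl genes in 36 libraries, and neither the read counter nor the gene annotation is stated. The deposited FPKM table holds 38992 genes, and the program that made it is not stated. Both tables list mouse genes and hold no parasite genes. Counts and FPKM of the same library had Spearman correlations across genes of 0.921 to 0.931, and 4.83% of values with at least 10 counts were listed at 0 FPKM. Symbols and coordinates came from the GENCODE vM21 annotation of GRCm38, which matched 26903 of the counted genes. The row of Gnai3 was incomplete in 9 libraries and was left out.

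Samples were grouped by their labels into 3 arms and 4 days, with 3 libraries each. The label ui was read as uninfected. Replicates 1 and 3 of the uninfected livers of day 39 differed by a chi-square of 2.35 per degree of freedom across genes, against at least 12.21 and a median of 32 among the other pairs of replicates. That is more than sampling noise and far less than any other pair, so their counts were summed as 1 sample and 35 samples were fitted in place of the planned 36. Replicate numbers did not pair samples across groups. Depth was 19039522 to 25700730 counts per library, and the floor used for groups at 0 was 3 counts over the group. These floors cover counting error only.

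Genes were tested with edgeR 4.0.16 under R 4.3.3. TMM scaling factors ranged from 0.899 to 1.504, genes were kept by filterByExpr with a minimum count of 10 (15813 tested, 11691 left out), and a quasi-likelihood model with robust spread was fitted to the means of 12 groups with 23 residual degrees of freedom. The common biological coefficient of variation was 0.181. Tests were quasi-likelihood F-tests, 2-sided, with Benjamini-Hochberg adjusted p under 0.05. Contrasts compared infected vehicle with uninfected livers, praziquantel with vehicle in infected livers, and praziquantel with uninfected livers at each day, and F-tests with 3 degrees of freedom tested whether effects, or uninfected livers, differed among days. SE of a log2 change was its size divided by the square root of F. Levels are read counts scaled to the library size after TMM (CPM) with the SD over samples.

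Before the data were examined, 43 gene lists of liver cell types, immune responses and metabolism were fixed (534 genes, 521 tested). Of these, 42 lists were tested, without the list of sex chromosome genes, of which 1 passed the filter. Each was tested with camera of limma 3.58.1 on log2 CPM (prior count 3, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the lists. Named genes followed a rule fixed at the same time. It admits the 5 risen and 5 fallen genes with the largest fitted fold among called genes with an average log2 CPM of at least 1 and no overlap between the libraries of both groups (chance gives 10% of genes without overlap for 3 against 3), up to 4 members with the smallest p of each list that was called or held at least 3 called genes, and 26 genes chosen in advance, each of which may be followed through days and arms. Paralogs with shared sequence, such as Chil3 and Chil4, the Saa and Cyp families and the Mup pseudogenes, cannot be separated with certainty by these counts.

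Alternatives were DESeq2 1.42.0 size factors in the edgeR test, the DESeq2 test, limma voom with sample weights, limma-trend on log2 of FPKM plus 1, no count filter, a replicate block, only the 6 libraries compared, each library left out in turn, and for lists an estimated correlation and fry. After seeing the data, 36 separate libraries, a clock score as covariate (Arntl, Npas2 and Clock minus Dbp, Nr1d1, Nr1d2, Tef, Hlf and Per3, mean log2 CPM), scaling by library size and, for day 39, the uninfected livers of the other days were added. For the tests among days, 1 replicate number was left out of every compared group in place of 1 library. Where leaving out libraries left a group with 1 sample, that sample was assumed to vary like the other groups.

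The pipeline was tested on simulated data for the praziquantel comparison of day 35, with 15435 genes. It called 18 of 49 genes shifted 1.5-fold, 34 of 50 shifted 2-fold, 37 of 48 shifted 4-fold and 48 of 49 shifted 8-fold, all in the right direction, and 8 of 15239 unshifted genes. A comparison without shifted genes gave 1 call. The shifted list was called, and 0 of the other 41 lists were. Genes were simulated independently of each other, so this does not test false list calls where the genes of a list move together. DESeq2 called 142 of the 196 shifted genes with 18 false calls, and limma voom 136 with 10. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.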

Results

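RNA was sequenced from livers of Swiss Webster mice, an outbred stock, at 32, 35, 39 and 46 days after infection with Schistosoma mansoni, the blood fluke whose eggs lodge in the liver. The 36 libraries formed 12 groups of 3, from 3 arms at 4 days. The arms were mice given vehicle without infection (labelled ui, read here as uninfected), infected mice given the vehicle Cremophor EL, and infected mice given praziquantel, the standard drug against the worm, at 250 mg/kg. Gavage ran from day 32 to day 35, and the labels do not say how many doses a liver of day 32 or 35 had received when it was taken. Total counts per library ranged from 19039522 to 25700730. The labels do not state that each library came from a separate mouse, so p-values measure only the spread between libraries. Replicates 1 and 3 of the uninfected livers of day 39 were nearly identical and were summed, which left 2 samples in that group.

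Uninfected livers were compared across days as the background for the other comparisons. At day 39 their clock genes were in a different phase from the other days. Dbp, a clock output gene, averaged 3.75 CPM (read counts scaled to the library size after TMM) at day 39 (n = 2), against 132, 121 and 78.7 CPM at days 32, 35 and 46 (n = 3 each). Arntl, the activator of the clock loop (ENSMUSG00000055116, GRCm38 chromosome 7, 113207465 to 113314126), was at 40.1 CPM at day 39 against 1.33, 1.6 and 7.2 CPM. Across the 4 days, 3071 of 15813 tested genes differed among uninfected livers, and 3276 genes differed between days 39 and 32 (1666 higher and 1610 lower at day 39). Between days 35 and 32 the count was 27, and between days 46 and 32 it was 1376. The count across days was 660 without replicate 1 and 1390 without replicate 2 of each uninfected day, and 177 with a clock score as covariate. It was 537 with a replicate block and 5130 with limma voom. Comparisons of day 39 therefore contain a difference in clock genes, since infected vehicle livers of that day had Dbp at 30 CPM and praziquantel livers at 52.9 CPM. Clock genes also differed at day 46, with a score (log2 units) of -1.98 in infected vehicle livers against -3.96 in uninfected ones and Dbp at 15.8 against 78.7 CPM. At day 35 the score was -3.2 with praziquantel and -4.7 with vehicle.

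**Figure D1:**
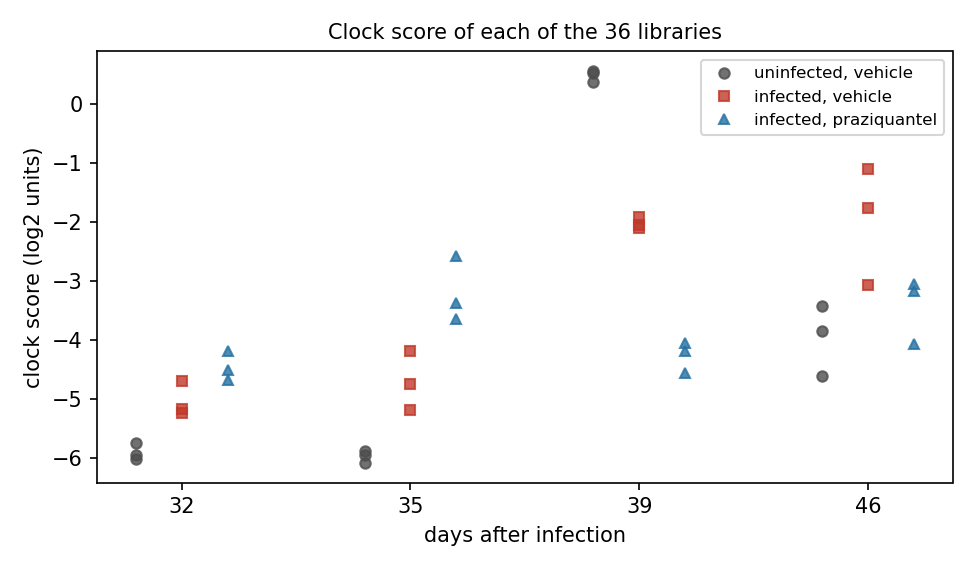
Clock score of each library (log2 units, vertical axis) by day after infection (horizontal axis), with 1 point per library and 1 colour per arm. Uninfected livers of day 39 averaged 0.48, against -5.9, -5.96 and -3.96 at days 32, 35 and 46.

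The comparison of infected with uninfected livers at day 32 asked what infection had changed by the first sampled day, and immune genes were among the rises. Cxcl9, a chemokine induced by interferon gamma that attracts T cells (ENSMUSG00000029417, GRCm38 chromosome 5, 92321347 to 92328079), rose 8.71-fold, from 23.8 ± 5.64 to 208 ± 23 CPM (SD, n = 3 each; log2 change 3.12 ± 0.46 SE, adjusted p = 0.001). Chil4, a chitinase-like protein of alternatively activated macrophages (ENSMUSG00000063779, GRCm38 chromosome 3, 106201490 to 106219507), was at 4.13 ± 0.425 CPM against 0 counts, at least 98.6-fold higher (adjusted p = 0.0013), although reads of its paralog Chil3 may be assigned to it. Retnlg, expressed by neutrophils, rose by 3.48 ± 0.54 and the chemokine Ccl8 by 4.93 ± 0.73 (log2). Of 14 type 2 cytokine and chemokine genes 7 rose (8 adjusted over the list alone), among them the eosinophil attractant Ccl11 (3.13 ± 0.61; adjusted p = 0.11 on FPKM). Of 14 genes of alternatively activated macrophages 6 rose (10 over the list alone), among them the checkpoint ligand Pdcd1lg2 (3.24 ± 0.47; adjusted p = 0.075 on FPKM). Both lists were called at adjusted p = 4.3e-11, and adjusted p = 0.014 with an estimated correlation.

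Other immune lists of day 32 rose in part. Recruited monocyte genes rose in 7 of 12 (11 adjusted over the list alone), with Lgals3 up by 1.16 ± 0.21 and Itgax by 2.4 ± 0.39. T cell genes rose in 6 of 12 (11 over the list alone), and NK cell genes in 6 of 10 (8 over the list alone), with Gzma up by 2.49 ± 0.50. Matrix genes rose in 7 of 20 (17 over the list alone), including Postn (1.20 ± 0.23), while Col1a1 did not pass (0.81 ± 0.32, adjusted p = 0.16, and 0.032 from the 6 libraries alone). Genes of fatty acid oxidation fell in 5 of 18 (12 over the list alone), among them Acadl (-0.74 ± 0.14). Of 28 ABC transporters, the family the series title concerns, 4 fell (6 fell and 1 rose over the list alone), including the peroxisomal Abcd2 (-0.91 ± 0.19). The efflux pump gene Abcb1a fell as well (-1.13 ± 0.32, adjusted p = 0.043), but this call ended with any 1 of the 6 libraries left out (adjusted p from 0.064 to 0.16), without the count filter (0.094), with a clock score (0.12) and with library-size scaling (0.1). These 5 lists were called by camera with a preset correlation and lost the call with an estimated one (adjusted p = 0.057, 0.072, 0.069, 0.072 and 0.096 in that order). ABC transporters had adjusted p = 0.098 with an estimated correlation. In all camera called 23 lists at day 32, 2 with an estimated correlation and 24 with a replicate block, and fry called 19. Of 10 exocrine pancreas genes 6 fell, which rested on 1 uninfected library, replicate 3, where Ctrb1 was at 217.54 CPM against 0.05 and 0.13 CPM in the other replicates (log2 change of Ctrb1 -9.80 with and -0.22 without that library). Of 15813 genes, 560 rose and 147 fell (707, 79.2% risen; 90.8% with library-size scaling and 67.8% with DESeq2). The count was 265 and 234 without uninfected replicates 1 and 2, 244 and 205 without infected replicates 1 and 3, and 314 on FPKM or 1351 with limma voom.

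At day 35 the same question again gave rises of immune genes. Cxcl9 rose 5.5-fold, from 32.8 ± 13.7 to 180 ± 121 CPM (SD, n = 3 each; log2 change 2.46 ± 0.45 SE, adjusted p = 0.00066, and 0.075 from the 6 libraries alone). Chil4 averaged 5.92 CPM against 0.0158 CPM. Csf1r, the receptor that maintains macrophages (ENSMUSG00000024621, GRCm38 chromosome 18, 61100598 to 61132149), rose by 1.22 ± 0.16 (adjusted p = 2.1e-05). Kupffer cell genes rose in 8 of 10 (8 adjusted over the list alone), Vsig4 and Clec4f among them. Type 1 response genes rose in 11 of 14 (14 over the list alone), with Gbp2 up by 2.34 ± 0.46. B cell genes rose in 8 of 12 (10 over the list alone), with Ms4a1 up by 1.40 ± 0.30. With an estimated correlation, type 2, alternatively activated macrophage, dendritic cell, Kupffer cell and checkpoint genes had adjusted p = 0.043 and monocyte genes 0.044. Type 1 response and B cell genes lost the call (adjusted p = 0.07 and adjusted p = 0.058 with an estimated correlation). Matrix genes rose in 12 of 20 (17 over the list alone; adjusted p = 0.058 with an estimated correlation), among them Postn (1.49 ± 0.23) and Col3a1 (1.29 ± 0.25). Cell cycle genes rose in 4 of 16 (10 over the list alone; adjusted p = 0.3 with an estimated correlation), with the mitotic kinase gene Bub1 up by 3.59 ± 0.81 (adjusted p = 0.0039). Its call ended without infected replicate 2 (0.11), from the 6 libraries alone (0.074) and on FPKM (0.10, adjusted p = 0.97).

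Falls at day 35 were fewer than rises. The lipase gene Lipg fell by 1.12 ± 0.24 (adjusted p = 0.081 with a clock score). Of 28 ABC transporters 3 rose (3 rose and 2 fell over the list alone), among them the cholesterol exporter Abcg1 (0.81 ± 0.21). Its call ended without uninfected replicate 2 and infected replicates 2 and 3 (adjusted p = 0.13, 0.084 and 0.054), from the 6 libraries alone (0.13) and with a clock score (0.064). The list was not called (adjusted p = 0.078). In all 1136 genes rose and 126 fell (1262, 90% risen; 98.5% with library-size scaling, 95% on FPKM and 73% with DESeq2). The count was 699 without uninfected replicate 2, 766 without infected replicate 2, 707 on FPKM, 613 from the 6 libraries alone and 2122 with limma voom.

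At day 39 infected livers had 3042 called genes, 1887 higher and 1155 lower (62% risen; 88.8% with library-size scaling and 86.1% on FPKM), against 4023 with all 36 libraries kept apart. Cxcl9 rose 14-fold, from 32 ± 12.5 (n = 2) to 446 ± 185 CPM (SD, n = 3; log2 change 3.81 ± 0.56 SE, adjusted p = 4.1e-05). All 14 type 1 response genes rose (14 adjusted over the list alone), Gbp2 by 3.56 ± 0.57 and Irf1, their transcription factor, by 1.70 ± 0.24. Type I interferon genes rose in 11 of 13 (12 over the list alone), Isg15 by 2.17 ± 0.48. T cell genes rose in 11 of 12 (12 over the list alone), and B cell genes in 10 of 12 (12 over the list alone). Cell cycle genes rose in 14 of 16 (15 over the list alone), with Mki67, a proliferation marker, up by 2.37 ± 0.49. Matrix genes rose in 7 of 20 (9 over the list alone), Tgfb1 by 0.88 ± 0.14, Timp1 by 3.59 ± 0.79 and Col1a1 by 1.17 ± 0.37. Without the summed uninfected sample, adjusted p was 0.051 for Isg15, 0.057 for Timp1 and 0.16 for Col1a1, and for Col1a1 0.14 and 0.094 without uninfected replicate 2 and infected replicate 3. With a clock score as covariate Isg15 (2.41 ± 0.78, adjusted p = 0.081), Mki67 (2.60 ± 0.76, 0.053), Timp1 (2.87 ± 1.01, 0.11) and Col1a1 (0.67 ± 0.57, 0.56) did not pass, and without the count filter Col1a1 had adjusted p = 0.066. Camera called 20 lists at day 39, 0 of them with an estimated correlation, where adjusted p = 0.077 for the type 1, T cell and B cell lists, 0.27 for type I interferon, 0.2 for cell cycle and 0.35 for matrix. Fry called 19.

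Some genes of glucose metabolism were lower at day 39, beside the shift of the clock in the uninfected livers. G6pc, which releases glucose from the liver, fell by 1.88 ± 0.39 and Pck1, the first step of glucose synthesis, by 1.39 ± 0.34. Of 10 genes of glucose metabolism 4 fell (4 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation). The clock genes moved both ways, with Dbp higher by 3.01 ± 0.48 and Npas2 at -2.27 ± 0.38. Against the uninfected livers of the other days these turned round, to -1.84 for Dbp and 3.63 for Npas2, and G6pc did not pass (0.20, adjusted p = 0.61). With a clock score Dbp (0.95 ± 0.38) and Npas2 (-0.49 ± 0.61) did not pass, which are part of that score. Among 28 ABC transporters 3 rose and 6 fell (3 and 8 over the list alone; adjusted p = 0.35 with an estimated correlation), with Abcc1 up by 0.89 ± 0.18. Library-size scaling gave 3 risen and 1 fallen, FPKM 3 and 2. The gene count was 633 with a clock score as covariate, 6190 against the uninfected livers of the other days, 4759 with limma voom, and 1053, 1757 and 1818 without the summed uninfected sample, uninfected replicate 2 and infected replicate 3.

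At day 46 macrophage and matrix genes were among the largest rises in infected livers. Retnla, an effector of alternatively activated macrophages (ENSMUSG00000061100, GRCm38 chromosome 16, 48842551 to 48844461), rose 347-fold, from 0.329 ± 0.218 to 117 ± 42.9 CPM (SD, n = 3 each; log2 change 8.44 ± 0.67 SE, adjusted p = 1.4e-10). Timp1, an inhibitor of matrix breakdown (ENSMUSG00000001131, GRCm38 chromosome X, 20870166 to 20874735), rose 285-fold, from 0.282 ± 0.0614 to 81.8 ± 41.2 CPM (log2 change 8.15 ± 0.60, adjusted p = 2.8e-11). Col1a1, the main fibrillar collagen of scars (ENSMUSG00000001506, GRCm38 chromosome 11, 94936224 to 94953042), rose 39.6-fold, from 11.3 ± 3.56 to 447 ± 91 CPM (log2 change 5.31 ± 0.38, adjusted p = 2e-11). The type 2 cytokine Il13 was at 1.96 CPM against 0 counts, at least 42.6-fold higher, and the eosinophil granule gene Epx at 7 CPM against 0 counts, at least 152-fold higher. All 20 matrix genes rose (20 adjusted over the list alone), as did all 14 type 2 genes, 9 eosinophil genes, 12 monocyte genes and 16 cell cycle genes. Of 12 stellate cell genes 9 rose and 1 fell, with equal counts adjusted over the list alone. Acta2, the marker of contractile myofibroblasts, rose by 1.85 ± 0.23, whereas Arg1, also expressed by hepatocytes, did not pass (0.05 ± 0.17; called at 0.51 with library-size scaling).

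**Figure D2:**
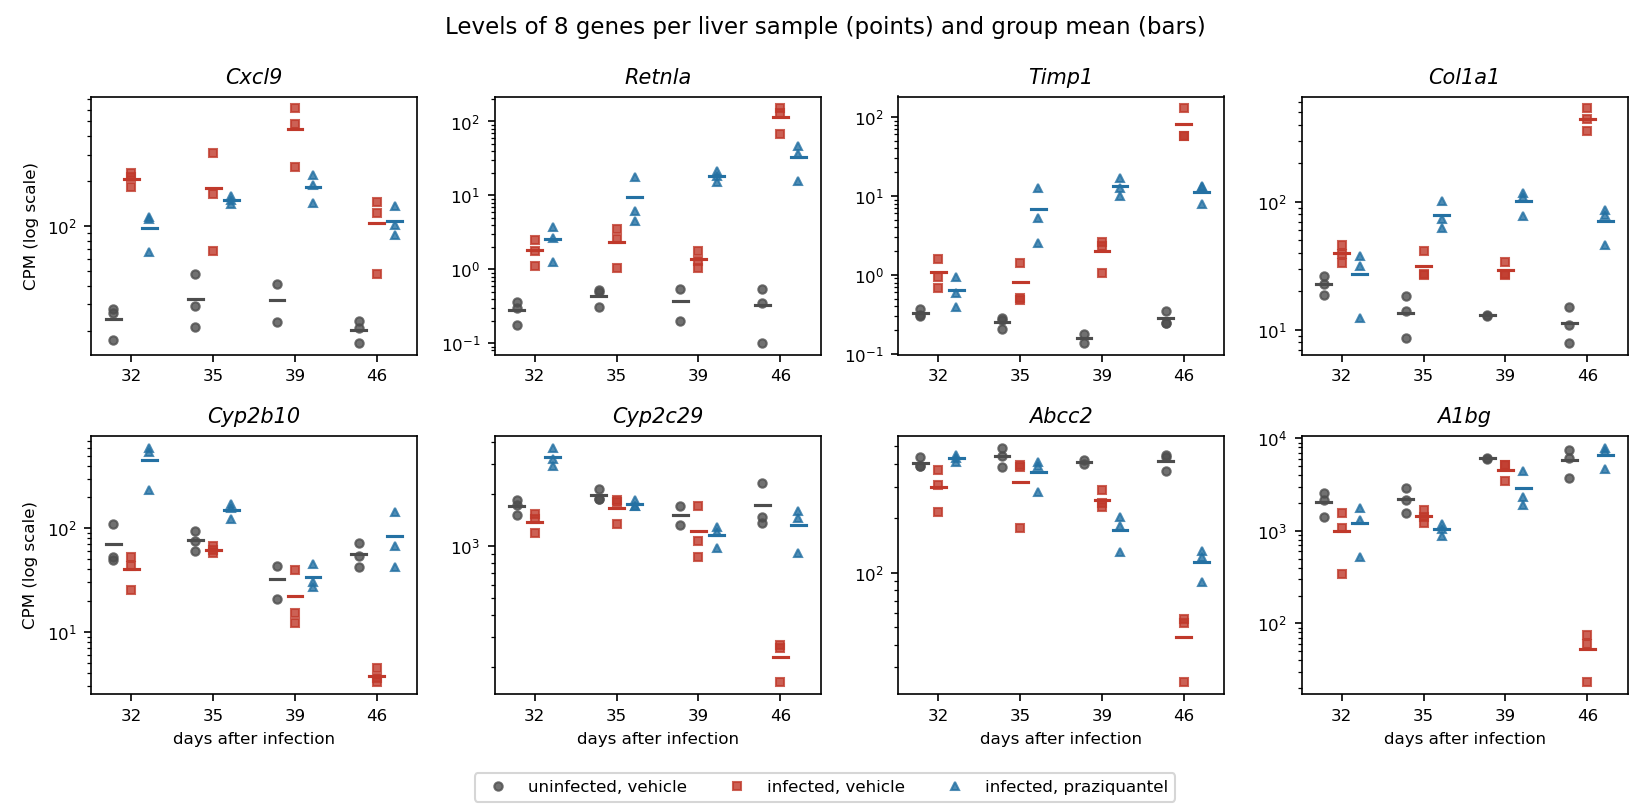
Levels of 8 genes (CPM, log vertical axis) by day after infection, with 1 point per sample, bars at group means and 1 colour per arm. In infected vehicle livers of day 46 Col1a1 averaged 447 CPM and Abcc2 44.3 CPM, against 11.3 and 417 CPM in uninfected livers.

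Genes of the hepatocyte's own tasks fell at day 46. A1bg, a plasma glycoprotein (ENSMUSG00000022347, GRCm38 chromosome 15, 60896859 to 60923012), was 109-fold lower, at 53.1 ± 27 against 5780 ± 1860 CPM (SD, n = 3 each; log2 change -6.77 ± 0.59 SE, adjusted p = 4.2e-10). Of 20 drug-metabolising cytochrome P450 genes 15 fell and 1 rose (15 and 1 adjusted over the list alone), including Cyp2c29 (-2.91 ± 0.25) and Cyp2e1 (-1.70 ± 0.20), and Cyp3a11 did not pass (-0.39 ± 0.39; called at -1.21 with a clock score). Of 28 ABC transporters 19 fell and 4 rose (19 and 4 over the list alone; 16 and 7 with library-size scaling). Abcc2, which pumps conjugates into bile (ENSMUSG00000025194, GRCm38 chromosome 19, 43782192 to 43840740), was 9.39-fold lower, at 44.3 ± 17 against 417 ± 46 CPM, Abcb1a fell by 1.31 ± 0.36, and Abcg1 rose by 2.17 ± 0.21. All 12 genes of lipogenesis fell, as did 14 of 18 of fatty acid oxidation, with Ppara down by 3.45 ± 0.38. So did 9 of 10 genes of glucose metabolism and 11 of 14 of the urea cycle list, with Otc (-2.12 ± 0.14); these counts are equal adjusted over the list alone. Alb, the albumin gene, fell by 0.92 ± 0.23 (0 on FPKM, and adjusted p = 0.17 from the 6 libraries alone). Abcb1a did not pass on FPKM, with a clock score, with library-size scaling or from the 6 libraries alone. The acute phase gene Lcn2 rose by 6.28 ± 0.54. Of 15813 genes 5238 rose and 4953 fell (10191, 51.4% risen; 76% with library-size scaling and 73.2% on FPKM). Scaling by library size moved the median of all genes to 0.45 and FPKM to 0.20 (log2), so the split of directions depended on the scaling. Which scaling is nearer to the real levels was not tested. Camera called 32 lists, 0 with an estimated correlation (adjusted p = 0.099 for the matrix, type 2, monocyte, P450, ABC transporter and glucose lists, 0.14 for the eosinophil and stellate cell lists and 0.24 for the cell cycle, lipogenesis and fatty acid oxidation lists, and 0.21 for the urea cycle list), and fry called 36.

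The effect of infection differed among days. A test across the 4 days called 6022 genes, and the difference between the effects at days 46 and 39 was called for 4696 (2090 higher and 2606 lower at day 46). The matrix list had a median difference of 2.38 (log2, 20 genes) between days 46 and 39 (adjusted p = 5.9e-21; adjusted p = 0.073 with an estimated correlation). The P450 list differed by a median of -1.50 (adjusted p = 6.8e-05; adjusted p = 0.097 with an estimated correlation). The count across days was 3697 and 3068 without replicates 2 and 3 of each group.

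**Figure D3:**
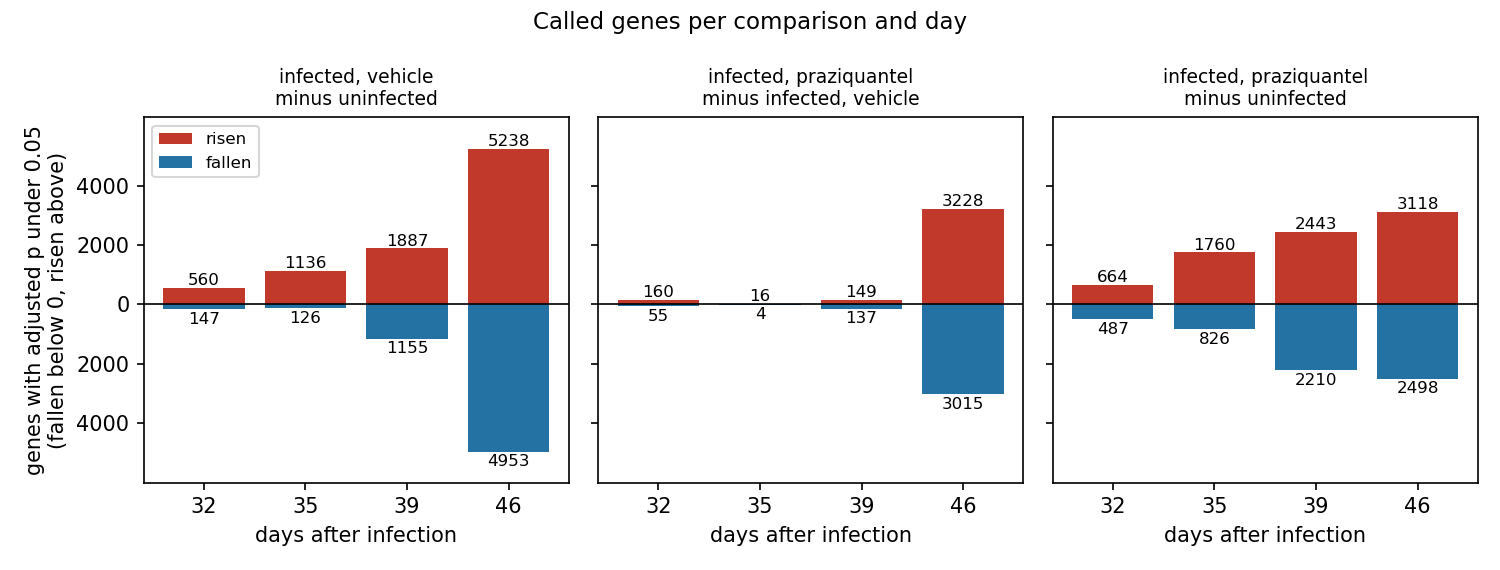
Genes with adjusted p under 0.05 (vertical axis, risen above 0 and fallen below) by day after infection, in 1 panel per comparison. Infection against no infection went from 707 genes at day 32 to 10191 at day 46, and praziquantel against vehicle from 215 to 6243.

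Praziquantel against vehicle in infected livers asked what differed in the host liver with treatment. No uninfected mice were given praziquantel, so an effect of the drug on the liver cannot be told apart from its effect on the worms. At day 32, some genes of drug metabolism rose, and lists of immune genes were called downward with the preset correlation only. Cyp2b10, a target of the xenobiotic receptor CAR (ENSMUSG00000030483, GRCm38 chromosome 7, 25897620 to 25926624), rose 11.3-fold, from 40.5 ± 14 to 460 ± 197 CPM (SD, n = 3 each; log2 change 3.50 ± 0.49 SE, adjusted p = 0.00053). Cyp2c55 rose by 3.63 ± 0.62, Cyp2c29 by 1.24 ± 0.24 and Cyp3a11, a target of the xenobiotic receptor PXR, by 1.78 ± 0.40, although reads may be shared among Cyp2b, Cyp2c and Cyp3a paralogs. Of 20 P450 genes 5 rose (7 adjusted over the list alone; adjusted p = 2.1e-05 by camera and adjusted p = 0.2 with an estimated correlation). Gadd45b also rose, by 2.73 ± 0.44, as did the phosphatase gene Dusp8 by 2.74 ± 0.40 and the immediate early gene Jun by 1.57 ± 0.34. Of 10 genes of the immediate early and heat shock list 3 were called (3 over the list alone; adjusted p = 0.42 with an estimated correlation). The call of Cyp3a11 ended without vehicle replicates 1 and 3 and praziquantel replicates 1, 2 and 3 (adjusted p = 0.14, 0.13, 0.082, 0.053 and 0.06), without the count filter (0.06) and with a clock score (0.051). The call of Jun ended without vehicle replicates 1, 2 and 3 and praziquantel replicate 1 (adjusted p = 0.095, 0.068, 0.059 and 0.12), with a replicate block (0.059) and with library-size scaling (0.054). From the 6 libraries alone the calls of Cyp2b10 (0.06), Cyp2c55 (0.08), Cyp3a11 (0.1), Gadd45b (0.12) and Dusp8 (0.082) ended at nearly equal folds. Camera called 16 lists, 5 upward and 11 downward. Those downward were T cell, NK cell, B cell, dendritic cell, Kupffer cell, monocyte, type 1, type 2, checkpoint, matrix and endothelial genes, with medians from -1.01 (B cell) to -0.19 (endothelial). With an estimated correlation their adjusted p was 0.42 to 0.55, and fry called the P450 list alone. Their members did not pass one by one, such as Cxcl9 (-1.09 ± 0.43, adjusted p = 0.2). The transporter genes Abcb1a (0.15 ± 0.32) and Abcc2 (0.52 ± 0.26) did not pass.

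At day 32 with praziquantel 160 genes rose and 55 fell (215, 74.4% risen; 44.2% with library-size scaling and 52.4% on FPKM). Leaving out 1 library gave 52 and 73 without vehicle replicates 1 and 3, and 30 and 82 without praziquantel replicates 1 and 3. The count was 63 on FPKM, 77 with library-size scaling, 92 from the 6 libraries alone, 109 without the count filter, 114 with a clock score, 509 with DESeq2 and 907 with limma voom.

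At day 35 few genes passed, among them genes of macrophages and matrix. The protease inhibitor A2m (ENSMUSG00000030111, GRCm38 chromosome 6, 121635376 to 121679227) was at 16.4 ± 19.2 against 0.46 ± 0.098 CPM (SD, n = 3 each; log2 change 5.16 ± 0.98 SE, adjusted p = 0.029), with an SD larger than its mean. Timp1 rose from 0.811 ± 0.539 to 6.78 ± 5.18 CPM (3.06 ± 0.52, adjusted p = 0.016) and Lox, which crosslinks collagen, from 1.13 ± 0.54 to 4.95 ± 1.32 CPM (2.13 ± 0.38, adjusted p = 0.016). Of 20 matrix genes 2 rose, Timp1 and Lox (8 adjusted over the list alone; adjusted p = 1.7e-08, and adjusted p = 0.3 with an estimated correlation). Of 12 monocyte genes 2 rose, Mmp12 (1.8 ± 0.36) and Gpnmb (6 over the list alone; adjusted p = 0.16 with an estimated correlation). Cell cycle genes such as Plk1 did not pass one by one (1.83 ± 0.45, adjusted p = 0.096, and 0.02 with DESeq2), with 12 of 16 risen adjusted over the list alone (adjusted p = 0.16 with an estimated correlation). Cyp2b10 no longer passed (1.28 ± 0.45, adjusted p = 0.32). The 4 fallen genes were Hhex (-0.87 ± 0.16), Sult5a1 (-2.36 ± 0.48) and the pseudogenes Mup-ps12 and Mup-ps13. With edgeR 16 genes rose and 4 fell, with DESeq2 103 and with limma voom 77 were called. There were 35 with all 36 libraries kept apart, 11 without the count filter, 2 from the 6 libraries alone and 1 with a clock score. The edgeR count was 0 without vehicle replicate 1, vehicle replicate 2 or praziquantel replicate 2 (1519, 1664 and 854 genes at unadjusted p under 0.05), and 12 without vehicle replicate 3. Calls also ended without vehicle replicate 3 for A2m (adjusted p = 0.13), Hhex (0.059) and Sult5a1 (0.065), and without praziquantel replicate 1 for Mmp12 (0.072) and Hhex (0.08). Without praziquantel replicate 3 they ended for Gpnmb (0.095), Sult5a1 (0.11) and Mup-ps13 (0.058). With a clock score or from the 6 libraries alone, the called genes named here did not pass. A2m, Lox, Gpnmb and Hhex did not pass on FPKM, nor A2m, Mmp12, Gpnmb and Sult5a1 without the count filter. With limma voom A2m, Timp1 and Gpnmb, with library-size scaling Gpnmb and Hhex, and with a replicate block A2m did not pass.

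At day 39, some macrophage and matrix genes were higher with praziquantel than with vehicle. Chil3, a chitinase-like protein of alternatively activated macrophages (ENSMUSG00000040809, GRCm38 chromosome 3, 106147554 to 106167564), rose 31.5-fold, from 1.91 ± 0.894 to 60.9 ± 16.3 CPM (SD, n = 3 each; log2 change 4.98 ± 0.75 SE, adjusted p = 0.00092). Retnla rose 13.2-fold (3.72 ± 0.53, adjusted p = 0.00037), and Col1a1 rose 3.47-fold, from 29.3 ± 3.98 to 102 ± 21.8 CPM (1.79 ± 0.32, adjusted p = 0.0029). Of 20 matrix genes 8 rose (11 adjusted over the list alone), among them Timp1 (2.72 ± 0.44) and Lox (2.14 ± 0.35). Of 14 genes of alternatively activated macrophages 4 rose (5 over the list alone), with adjusted p = 0.73 with an estimated correlation for both lists. The medians of the Kupffer cell (-0.05 ± 0.11), stellate cell (0.05 ± 0.14) and recruited monocyte lists (0.14 ± 0.25) were near 0, with SE over the genes of each list. Camera still called the recruited monocyte list, in which Mmp12 (1.83 ± 0.35) and Trem2 (1.73 ± 0.37) rose. It called 9 lists, 6 upward and 3 downward, and 0 with an estimated correlation, while fry called 2. Clock genes differed as well, with Arntl at 3.01 ± 0.616 against 14.4 ± 2.17 CPM. The deubiquitinase gene Usp2, whose level follows the clock, rose by 3.22 ± 0.42. Tef rose (1.2 ± 0.17) and Nr1d1 fell (-1.86 ± 0.27), although both are subtracted in the clock score. The score may therefore capture the clock difference of this comparison in part only. Type 1 response genes did not pass one by one (Cxcl9 -1.28 ± 0.43, adjusted p = 0.12; 0.04 with DESeq2 and 0.017 with limma voom), with 2 of 14 fallen over the list alone. In all 149 genes rose and 137 fell (286), and 4 were called with a clock score as covariate, where Col1a1 (1.34 ± 0.51, adjusted p = 0.61), Timp1 (2.08 ± 0.67, 0.46), Lox (2.16 ± 0.57, 0.28), Retnla (3.43 ± 0.80, 0.18), Usp2 (2.03 ± 0.57, 0.33) and Arntl (-0.39 ± 0.30, 0.89), part of the score, did not pass, and Chil3 did (6.42 ± 1.09, 0.029). These changes kept their direction and, apart from Arntl, had larger SE than without the score. The count was 146 and 117 without vehicle replicates 1 and 2, 175, 118 and 171 without praziquantel replicates 1, 2 and 3, 170 with library-size scaling, 175 on FPKM, 595 with DESeq2 and 1245 with limma voom.

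At day 46 praziquantel livers differed from vehicle livers in the opposite direction for matrix genes. All 20 matrix genes were lower (20 adjusted over the list alone; adjusted p = 8.7e-19, and adjusted p = 0.043 with an estimated correlation). Col1a1 was 6.32-fold lower, at 70.7 ± 21.7 against 447 ± 91 CPM (SD, n = 3 each; log2 change -2.66 ± 0.33 SE, adjusted p = 8.4e-07). Timp1 was at 11.3 ± 3 against 81.8 ± 41.2 CPM (-2.85 ± 0.41). Retnla fell by 1.83 ± 0.43 and Acta2 by 1.34 ± 0.22. Stellate cell genes fell in 10 of 12 (11 over the list alone), Pdgfra by 1.62 ± 0.17. Monocyte genes fell in 11 of 12 (12 over the list alone), with Lgals3 down by 1.83 ± 0.21. Type 2 genes fell in 8 of 14 (9 over the list alone), with Ccl11 down by 2.81 ± 0.38 and Il13 by 2.48 ± 0.51. Acute phase genes fell in 13 of 18 (14 over the list alone), with Lcn2 down by 3.78 ± 0.47. Camera with an estimated correlation gave adjusted p = 0.043 for stellate cell, 0.13 for monocyte, 0.12 for type 2 and 0.35 for acute phase genes.

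Hepatocyte genes rose in the same comparison of day 46. A1bg was 125-fold higher, at 6620 ± 1730 against 53.1 ± 27 CPM (SD, n = 3 each; log2 change 6.96 ± 0.59 SE, adjusted p = 3.2e-09). Of 20 P450 genes 16 rose and 1 fell (18 and 1 adjusted over the list alone; adjusted p = 0.043 with an estimated correlation), including Cyp2c29 (2.53 ± 0.25) and Cyp2b10 (4.49 ± 0.53). Of 28 ABC transporters 18 rose and 3 fell (18 and 4 over the list alone; adjusted p = 0.1 with an estimated correlation; 11 and 4 with library-size scaling). Abcc2 rose from 44.3 ± 17 to 115 ± 22.7 CPM (1.37 ± 0.26, adjusted p = 0.00017). The peroxisomal Abcd3 rose by 2.11 ± 0.19, Abcb1a by 1.43 ± 0.35 and Abcg2 by 0.54 ± 0.14. Abcg2 did not pass with library-size scaling or on FPKM and Abcb1a not from the 6 libraries alone (adjusted p = 0.063). Fatty acid oxidation genes rose in 16 of 18 (16 over the list alone; adjusted p = 0.17 with an estimated correlation). Lipogenesis genes rose in all 12 (12 over the list alone; adjusted p = 0.18 with an estimated correlation). Glucose genes rose in 8 of 10 (8 over the list alone; adjusted p = 0.045 with an estimated correlation), with G6pc up by 2.4 ± 0.37. Of 15813 genes 3228 rose and 3015 fell (6243, 51.7% risen; 17% with library-size scaling and 22.4% on FPKM, which moved the median of all genes to -0.32 and -0.12), and 3365 were called from the 6 libraries alone.

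**Figure D4:**
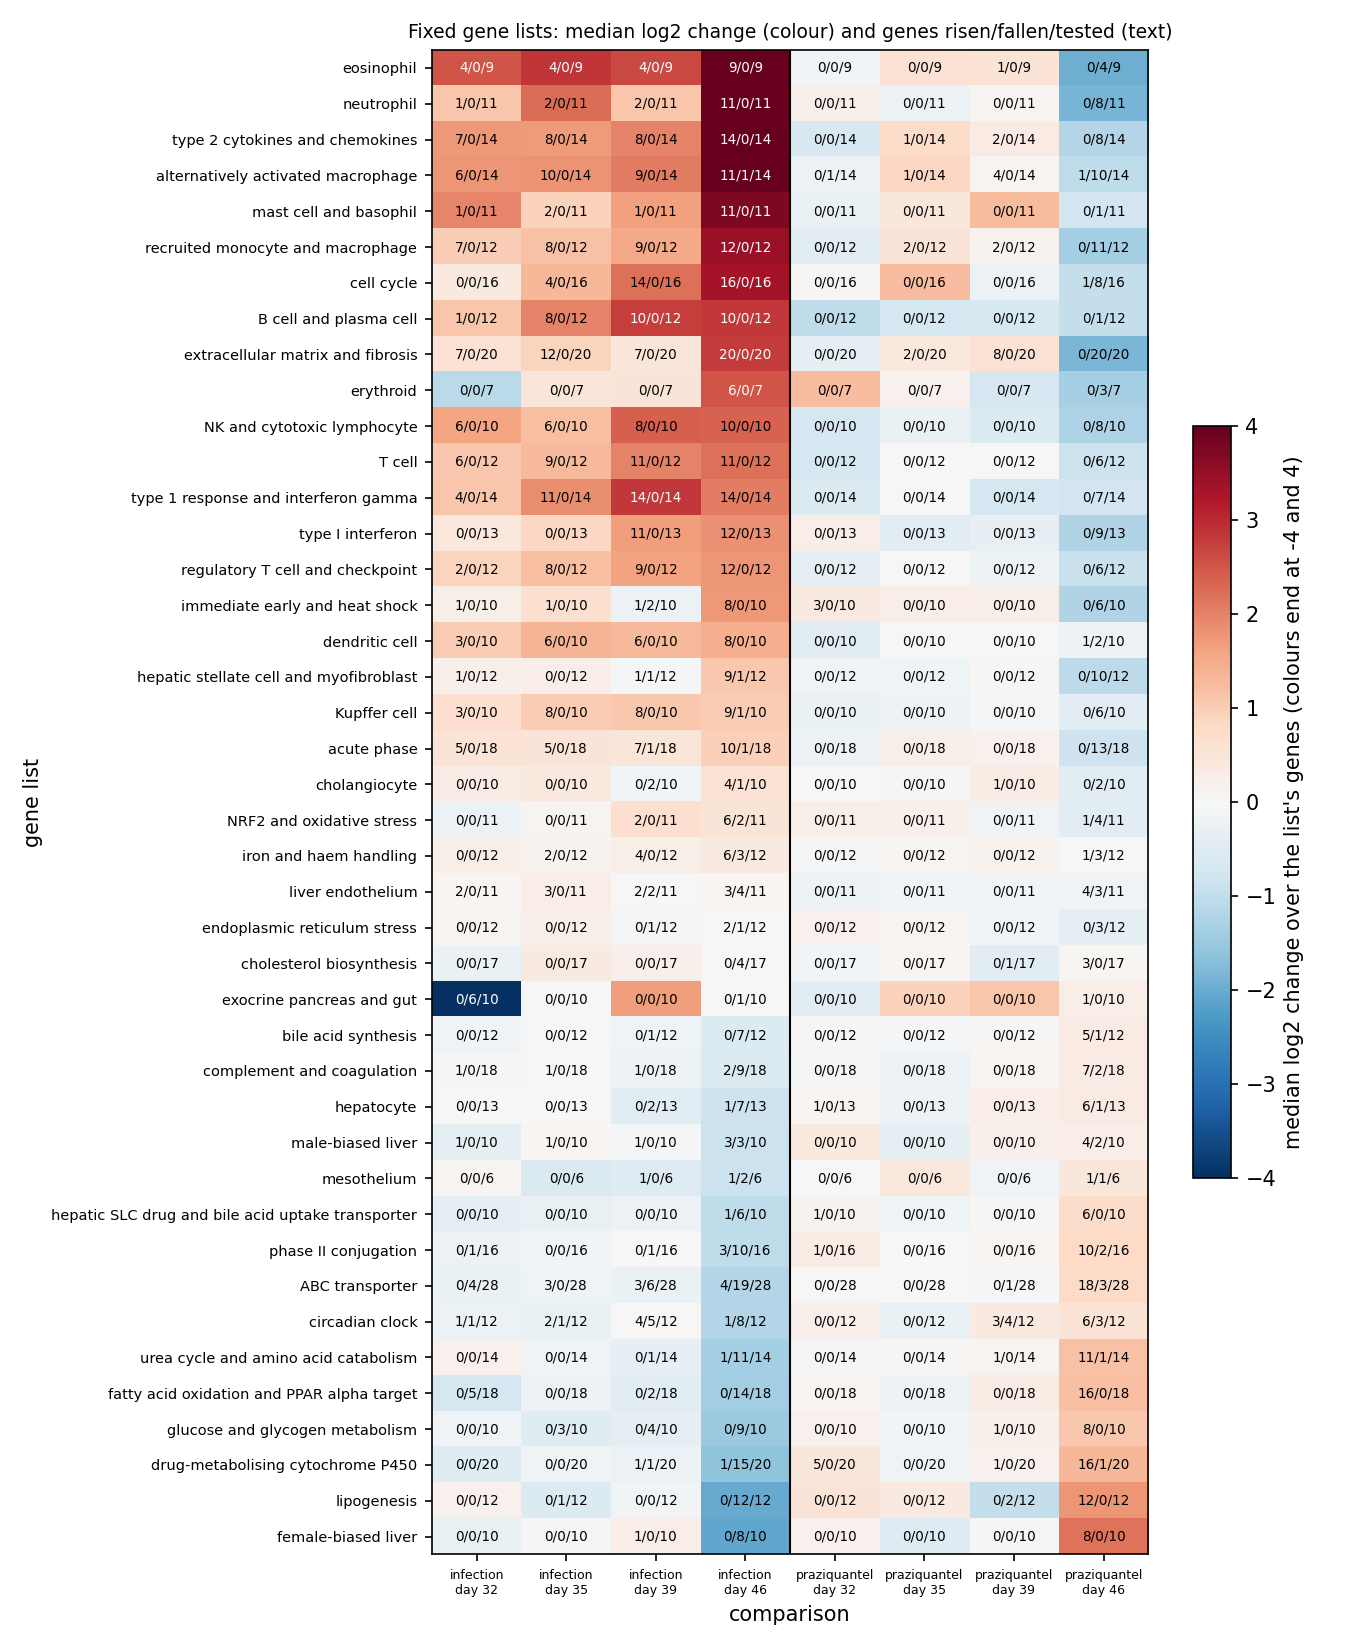
Median log2 change (colour) and numbers of genes risen, fallen and tested (text) for the fixed gene lists (vertical axis) in infection and praziquantel comparisons by day (horizontal axis). At day 46 all 20 matrix genes were higher with infection and lower with praziquantel.

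Praziquantel effects differed among days as well, with 4881 genes called across the 4 days and 4487 between days 46 and 39 (2455 higher and 2032 lower at day 46). The matrix list differed between those days by a median of -2.43 (log2, 20 genes; adjusted p = 2.7e-23, and adjusted p = 0.045 with an estimated correlation). Col1a1 differed by -4.45 ± 0.46 (adjusted p = 2.1e-07) and Timp1 by -5.57 ± 0.60 (adjusted p = 3.5e-07). Retnla differed by -5.54 ± 0.68 and Chil3 by -6.65 ± 0.97. The P450 list differed by a median of 1.27 (adjusted p = 3.6e-05; adjusted p = 0.085 with an estimated correlation). The count across days was 3186 and 2472 without replicates 1 and 2 of each group.

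Praziquantel livers were also compared with uninfected livers, to show what remained or arose under treatment. At day 32 Cyp2b10 was higher by 2.71 ± 0.47 (log2 ± SE, adjusted p = 0.0012) and the stress gene Atf3 by 2.61 ± 0.29 (adjusted p = 1.3e-05), and 1151 genes differed (664 higher, 487 lower). Col1a1 did not pass at day 32 (0.27, adjusted p = 0.68) and was higher by 2.54 ± 0.34, 2.97 ± 0.40 and 2.65 ± 0.34 at days 35, 39 and 46. Timp1 was higher by 4.70 ± 0.62, 6.30 ± 0.72 and 5.30 ± 0.60 at the same days. Matrix genes were higher in 1, 16, 15 and 18 of 20 at days 32, 35, 39 and 46, and type 2 genes in 3, 11, 10 and 11 of 14. Abcc2 was lower at day 39 (-1.25 ± 0.28, adjusted p = 0.0015) and day 46 (-1.86 ± 0.27, adjusted p = 1.6e-05), while A1bg at day 46 did not pass (0.19 ± 0.46, adjusted p = 0.77). Of 20 P450 genes 4 were lower and 0 higher at day 46, and of 28 ABC transporters 9 were lower and 2 higher.

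The counts of genes at days 35, 39 and 46 in that comparison were 2586 (1760 higher, 68.1%), 4653 (2443 higher, 52.5%) and 5616 (3118 higher, 55.5%). Library-size scaling gave 91.1%, 76.6% and 72.3% higher and FPKM 84.4%, 73.2% and 72.8%. With all 36 libraries apart day 39 gave 5723. With a clock score as covariate the counts were 142, 558 and 1 at days 32, 35 and 39, and at day 39 Col1a1 (2.01 ± 0.92), Timp1 (4.94 ± 1.37) and Abcc2 (-0.54 ± 0.77) did not pass, with larger SE than without the score. The day 32 count was 628 on FPKM, 719 without the count filter, 720 with library-size scaling and 2504 with limma voom, which gave 4397 at day 35. It was 445, 715 and 639 without uninfected replicates 1, 2 and 3, and 339 and 553 without praziquantel replicates 1 and 3. The day 35 count was 1371 without praziquantel replicate 2, and the day 39 count 2127 without the summed uninfected sample. Of the 5238 genes that rose with infection at day 46, 2775 fell with praziquantel and 1379 of those were still above uninfected livers. Of the 4953 that fell, 2825 rose with praziquantel and 1115 were still below. Both contrasts share the infected vehicle livers, so that part of this overlap may come from them.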

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

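The tests of a single mislabelled library and of a lower share of hepatocytes, and the fits with a clock score or library-size scaling, were chosen only after the result was seen. Effects that differed between days drew a closer look. The infection effect differed across the 4 days for 6022 genes, and between days 46 and 39 for 4696. The praziquantel effect differed across the 4 days for 4881 genes, and between days 46 and 39 for 4487. Macrophage, matrix and type 2 cytokine genes were among those that differed. The praziquantel effect on Retnla was lower at day 46 than at day 39 by a log2 difference of -5.54 ± 0.68 (SE, adjusted p = 2.7e-06), on Chil3 by -6.65 ± 0.97 (adjusted p = 2.6e-05), on Timp1 by -5.57 ± 0.60 (adjusted p = 3.5e-07), on Il13 by -5.24 ± 1.02 (adjusted p = 0.00058; under 0.3 CPM at day 39) and on Col1a1 by -4.45 ± 0.46 (adjusted p = 2.1e-07). The matrix list had a median difference of -2.43 over 20 genes. Each was tested as a difference of effects in edgeR.

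The first pattern is a reversal of some matrix and macrophage genes. With praziquantel 8 of 20 matrix genes and 4 of 14 genes of alternatively activated macrophages were higher at day 39 (adjusted p = 0.73 for both lists with an estimated correlation), and 20 and 10 were lower at day 46. The Kupffer cell and recruited monocyte lists had medians of -0.05 ± 0.11 and 0.14 ± 0.25 at day 39 (SE over list genes). Of the monocyte list Mmp12 (1.83 ± 0.35) and Trem2 (1.73 ± 0.37) rose. No single library made the difference between the days, since its median over the matrix list stayed at -2.24 or further from 0 with each of the 12 libraries left out. The fall of day 46 makes most of that difference, so it does not test the rise of day 39. The median of the matrix list at day 39 itself was 0.49 to 0.71 with 1 library left out. Matrix genes exceeded endothelial genes by a median of 0.71 ± 0.25 at day 39. That SE is over the genes of the lists and holds no spread between livers. These lists did not rise alike, which does not settle whether treated livers held a lower share of hepatocytes. Time of day stays open for the matrix genes at day 39. The clock score subtracts both Tef and Nr1d1, which went opposite ways in this comparison, so it may capture the clock in part only. With the clock score as covariate the median of their list was 0.24 against 0.59 without, the median SE of a gene was 0.35 against 0.22, and 0 matrix genes were called against 8. Single genes kept more of their change. Col1a1 had 1.34 ± 0.51 against 1.79 ± 0.32, Timp1 2.08 ± 0.67 against 2.72 ± 0.44 and Lox 2.16 ± 0.57 against 2.14 ± 0.35, and their calls ended with a wider SE. The macrophage gene Chil3 kept its call (6.42 ± 1.09 against 4.98 ± 0.75, adjusted p = 0.029), and Retnla did not (3.43 ± 0.80 against 3.72 ± 0.53). With the clock score the median of the difference between the days was -2.29 with 20 of 20 called, which holds the fall of day 46 and does not test the rise of day 39. An effect of the treatment on the liver stays open and untested.

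Infected livers of day 46 showed the second pattern, a change in most expressed genes with rises in macrophage, type 2 and matrix genes and falls in hepatocyte metabolism. It did not rest on a single library, as the lowest count with 1 of the 6 left out was 9404. A lower share of hepatocytes alone, with the other cell types in unchanged proportion, would raise the genes of those types alike. Recruited monocyte genes instead exceeded endothelial genes by a median of 3.36 ± 0.55 (SE over list genes, medians 3.45 and 0.09). Kupffer cell genes were at 1.00, stellate cell genes at 1.08 and cholangiocyte genes at 0.57. These medians go against such an even loss only. Cells entering the liver would also lower the share of hepatocytes, so falls of hepatocyte genes by composition stay open. The split of directions did depend on scaling, with 76% of called genes risen by library size against 51.4% by TMM. The 50 genes most abundant in uninfected livers of day 46 held 35.7% of counts there and 27.4% in infected vehicle livers of that day. Choosing them in the uninfected livers by itself favours a higher share there. An effect of infection on the liver's cells stays open, and its mechanism was not tested.

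A shift of clock genes in the uninfected livers of day 39 was the third. A single mislabelled library is argued against, since 3 of 3 libraries scored above all other uninfected libraries (lowest 0.37, highest other -3.42). The nearly identical replicates were summed in the fits, so these 3 libraries stand for only 2 samples. Replicate 2, the sample that was not summed, scored 0.37. Collection at another time of day stays open and cannot be told apart from other differences of that day. Of 3266 genes called between days 39 and 32, 71.2% changed as their slope on the clock score in the other groups predicts, but shuffled scores reached up to 71.7% (median 50.4%, 100 shuffles, 3 as large). The labels give no time of collection, and no biological explanation was tested.

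The libraries were regrouped to see how many genes other labels would call. For days, 80 labellings were used, counting the real one. The real labels gave 6022, 4881 and 3071 genes for infection, praziquantel and uninfected livers, against highest other counts of 603, 2591 and 190. Other labels mix unlike libraries in a group, which widens the spread and lowers their counts, so chance is not excluded by them. Of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. For infection the real counts and highest others were 707 and 0 at day 32, 1262 and 0 at day 35, and 10191 and 6 at day 46. For praziquantel they were 215 and 0 (day 32), 20 and 0 (day 35), 286 and 2 (day 39), and 6243 and 709 (day 46), and against uninfected livers 1151 and 0 (day 32), 2586 and 2 (day 35), and 5616 and 1 (day 46). For lists called with a preset correlation they were close, at 23 and 22 (day 32), 25 and 19 (day 35), and 32 and 30 (day 46) for infection, and 16 and 18, 12 and 18, 9 and 19, and 30 and 27 for praziquantel by day. Of the 10 splits, 2, 6 and 7 gave at least as many lists as the real one for praziquantel at days 32, 35 and 39. Comparisons with the uninfected livers of day 39 were not split, since 2 samples remained.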

How the results depend on the processing

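The clock score, the library-size scaling, the 36 separate libraries and the uninfected livers of the other days were chosen after seeing the data. Named genes kept their direction except for the 13 values given last, while the numbers of called genes moved. Among all called genes more turned sign. The settings where over 250 did so gave 861 of 10191 on FPKM (176 of them called) and 718 with library-size scaling (16 called) for infection at day 46, 254 of 3042 (81 called) for infection at day 39 against the uninfected livers of the other days, 286 of 6243 on FPKM (20 called) and 299 with library-size scaling (0 called) for praziquantel at day 46, 264 of 5616 on FPKM (25 called) against uninfected livers at day 46, and 787 of 4653 (0 called) for praziquantel against uninfected livers at day 39 with the clock score. Outside the values below, counts of genes and lists stayed within 1.5 times under each alternative run. The infection count of day 46 did so under every alternative run, with 9404 to 9885 genes when 1 library was left out. The cause of the changes below was not tested, except that the 6 libraries alone and a library left out leave fewer samples.

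Limma voom called fewer genes at day 46 (8704 for infection and 4982 for praziquantel) and gave 1351, 2122 and 4759 for infection at days 32, 35 and 39, 907, 77 and 1245 for praziquantel at days 32, 35 and 39, 2504 and 4397 for praziquantel against uninfected livers at days 32 and 35, and 5130 for uninfected livers across days. DESeq2 gave 509, 103 and 595 for praziquantel at days 32, 35 and 39. FPKM gave 314 and 707 for infection at days 32 and 35, 63 and 175 for praziquantel at days 32 and 39, and 628 for praziquantel against uninfected livers at day 32. Without the count filter 109 and 11 genes were called for praziquantel at days 32 and 35, and 719 against uninfected livers at day 32. Library-size scaling gave 77 and 170 for praziquantel at days 32 and 39, and 720 against uninfected livers at day 32. The 6 libraries alone gave 613 for infection at day 35, and 92, 2 and 3365 for praziquantel at days 32, 35 and 46. The clock score gave 633 for infection at day 39, 114, 1 and 4 for praziquantel at days 32, 35 and 39, 142, 558 and 1 against uninfected livers at those days, and 177 for uninfected livers across days, where a replicate block gave 537. With 36 libraries apart praziquantel at day 35 had 35 genes, and against the uninfected livers of the other days infection at day 39 had 6190.

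With 1 library left out, infection gave 205 to 740 genes at day 32, 699 to 1239 at day 35 and 1053 to 3033 at day 39. Praziquantel gave 30 to 238 at day 32, 0 to 28 at day 35, 117 to 193 at day 39 and 4881 to 5979 at day 46, and against uninfected livers 339 to 1019, 1371 to 2521, 2127 to 4238 and 3988 to 5160. Differences among days ranged from 3068 to 5278 for infection, 2472 to 3665 for praziquantel and 660 to 2162 for uninfected livers. For these differences among days, 1 replicate number was left out of every compared group at every day, which removes more than 1 library. The libraries or replicate numbers that moved a count by more than 1.5 times are named beside it in the report.

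Of the lists called with a preset correlation, an estimated correlation left 2, 6, 0 and 0 for infection and 0, 0, 0 and 6 for praziquantel at the 4 days, and fry called 1, 4 and 2 for praziquantel at days 32, 35 and 39. Against uninfected livers, praziquantel had 18, 24, 18 and 16 lists, and 0, 5, 0 and 0 with an estimated correlation, and 6 by fry at day 32. With 1 library left out, the list counts were 21 to 26, 22 to 26, 17 to 21 and 30 to 32 for infection, and 8 to 19, 10 to 20, 7 to 14 and 23 to 31 for praziquantel. The lowest of day 32 was without praziquantel replicate 2 (8), and the highest of days 35 and 39 were without praziquantel replicate 1 (20) and vehicle replicate 1 (14).

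For the named genes, 126 results had 2012 alternative values, of which 1850 stayed on the same side of the threshold in the same direction, 143 lost a call, 6 gained one and 13 turned sign, 9 of them in genes called under neither setting. Against the uninfected livers of the other days, infection at day 39 gave log2 changes of 0.20 for G6pc, -1.84 for Dbp and 3.63 for Npas2, the opposite directions, and on FPKM Alb at day 46 was at 0. The other 9 lay near 0. For infection at day 46 Arg1 was at -0.06 with limma voom and at -0.08 to 0.20 with 1 library left out, and Cyp3a11 at 0.03 on FPKM, 0 with library-size scaling and -0.65 to 0.04 with 1 library left out. With 1 library left out Abcb1a with praziquantel at day 32 was at -0.03 to 0.31, and against uninfected livers Col1a1 at day 32 was at -0.04 to 0.61 and A1bg at day 46 at -0.06 to 0.39. Depth limits genes under about 1 CPM, such as the cytokines Il4 and Il5, where a few counts decide.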

Other observations

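All tests and values here were chosen after the result was seen, except the tests of fixed gene lists. Neutrophil and metallothionein genes were among the changes of day 46. All 11 neutrophil genes rose with infection (11 adjusted over the list alone; adjusted p = 0.24 with an estimated correlation), Retnlg by 6.88 ± 0.61 (log2 ± SE), and 8 of 11 fell with praziquantel (8 over the list alone; adjusted p = 0.33 with an estimated correlation). The metallothionein genes Mt1 and Mt2, which bind metals under stress, rose with infection by 5.43 ± 0.64 and 6.27 ± 0.69 and fell with praziquantel by 3.91 ± 0.59 and 3.98 ± 0.60. Of 10 female-biased liver genes 8 fell with infection (8 over the list alone; adjusted p = 0.099 with an estimated correlation), with Cyp2b9 at -2.96 ± 0.21. With praziquantel 8 rose (8 over the list alone; adjusted p = 0.045 with an estimated correlation). Of 10 male-biased genes 3 rose and 3 fell with infection.

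Liver endothelial genes went both ways at day 46. Pecam1 rose with infection by 1.15 ± 0.11 and fell with praziquantel by 0.61 ± 0.10, whereas Kdr, a growth factor receptor of endothelium, fell with infection by 1.15 ± 0.12 and rose with praziquantel by 0.83 ± 0.11. Of 11 endothelial genes 3 rose and 4 fell with infection.

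Xist was at 354.66 to 1192.13 CPM in all 36 libraries and Ddx3y, from the Y chromosome, at 0.1 CPM at most, and the labels give no sex. Pancreas transcripts were seen in replicate 3 of the uninfected livers of day 32, with Ctrb1 at 217.54 CPM and Cela2a at 53.15 CPM, where the other replicates had 0.86 and 1.01 CPM of Cela2a. Mitochondrial genes took 1.68% of counts in infected vehicle livers of day 46 and 2.73% to 3.72% in the other groups.

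The contrasts of infection and praziquantel share the infected vehicle livers, which alone makes their effects correlate negatively. At day 46 the effects of infection and of praziquantel had a covariance of -0.995 across genes, against -0.0769 in simulated data without effects. At days 32, 35 and 39 the covariances were -0.12, -0.0197 and -0.24, against -0.0802, -0.0758 and -0.0858. The correlation at day 46 was -0.81, against -0.49 in simulated data. At days 32, 35 and 39 it was -0.34, -0.06 and -0.41, weaker than the simulated -0.5, -0.48 and -0.46. By correlation, opposed effects beyond the shared livers are not shown at those earlier days. By covariance, days 32 and 39 went beyond the simulated size and day 35 did not. The question therefore stays open at days 32 and 39, where these measures differ. Genes are not independent replicates. Of 167 genes called with praziquantel at both days 39 and 46, 49 went from risen to fallen and 49 from fallen to risen.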
